A study of Mus musculus with 6 samples.

How the data were processed

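RNA was measured in 6 samples of RAW264.7 cells, 3 labelled M1 and 3 labelled M0. Per the labels' protocols, libraries were made from poly(A)-selected RNA, and the duration of treatment is not given in the sources used here. The submitters' processing notes name bcl2fastq, STAR 2.7.5a, HOMER 4.11.1, DESeq2 and the genome build mm10, with no role or order. The authors deposited 2 tables. One holds TPM per gene and sample, per the file headers, for 25124 genes, with 1 row per gene symbol giving a RefSeq transcript, its coordinates and its length. Its columns sum to between 551257 and 572349, which is less than the full TPM scale. The other holds, per the file headers, 6 columns of log2 values (the transform is not stated) and the authors' log2 fold change, p-value and adjusted p-value of M1 against M0 for 24421 genes. The headers also give each library's total tags.

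The tests were fixed before the data were examined, with a count model as first choice and limma on TPM should raw counts be lacking. The deposited values are TPM, so the second was used: limma 3.58.1 (trend and robust empirical Bayes, R 4.3.3) on log2(TPM + 1) for genes at 1 TPM or more in at least 3 samples, 11297 in all, with group as the only term and 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Fold changes from limma are on the log2(TPM + 1) scale. Folds given as such are ratios of mean TPM. With 3 samples against 3 an exact permutation test of one gene cannot go below p = 0.10 and was not used for calls. Means and SDs are of TPM.

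TPM times transcript length came out as a whole multiple of one value per library, within 0.1 of a whole number, for 99.8% to 99.98% of the values above 0. That gave the reads behind each value. Reads in genes were 18110568, 18104946 and 15615639 in M0 replicates 1 to 3 and 19738950, 20283180 and 18666940 in M1 replicates 1 to 3. The genes above 0 numbered 15161 to 16774 per library. Read numbers cover counting error only. Coordinates are those of the deposited table. Of 25124 identifiers 25000 were found in RefSeq GRCm38.p6, and 16793 had the same start there, against 3 with a start lower by 1, so the coordinates count from 1. The counting's use of strand is not given in the sources used here. Mir7676-1 and Mir7676-2, on opposite strands at the same coordinates, had identical means and SDs, so strand was not used for that pair. Overlapping and antisense genes, and near-identical copies, are therefore uncertain. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 1.55 to 7.90), so each sample counted once.

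For 49 gene lists fixed before the data were examined, tested members were counted past the threshold over all genes and adjusted over the list alone, and 41 lists with at least 5 tested members were tested with camera (preset correlation 0.01). Of 18 lists called higher, inflammatory cytokines, interferon-stimulated antiviral genes, guanylate-binding proteins and immunity-related GTPases, MHC class I presentation and M1 markers kept their call with an estimated correlation. None of the 41 was called with an estimated correlation after rescaling. On the TPM scale, counts adjusted over the list alone equalled those over all genes except in the lysosome (6 and 24), cytosolic ribosomal protein (1 and 4) and ribosome biogenesis (7 and 8) lists, higher before lower. Genes were named by a rule set at the same time: the 10 largest fitted changes in each direction among called genes with a mean of at least 10 TPM in the higher group and no overlap between groups, passing over predicted genes and small RNAs; up to 2 rising and 2 falling members with the smallest p in each list described, with the most abundant member not called; and 21 genes whatever their values. Some genes that this rule takes are not reported here. Which lists were described with examples was chosen after the results were seen. Lck, Batf3, H2-Aa, H2-Ab1, H2-Eb1 and the microRNA rows were also named after their values were seen.

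The procedure was tested on simulated data with 200 genes changed by known folds, in 10 draws of 11193 to 11234 tested genes. An earlier single draw used the median over genes as the dispersion, which fell on its lower limit of 0.001, and gave 4.55% false calls. Because a median of variances from 3 samples runs low, a trimmed mean (0.00169) was then tried, and a single draw gave 8.65%. Both were rerun over 10 draws. With the median, false calls averaged 6.26% of calls (4.00% to 8.57%), and with the trimmed mean 6.44% (4.02% to 8.65%). In these draws the false share ran somewhat above the nominal 5% and differed little between the dispersions, which lie close together. All genes shared a single dispersion, and 200 were changed, whereas 9055 were called in the data. The false share among that many calls was not tested. With the trimmed mean, 90.1% of genes changed 1.5-fold were recovered, 96.9% at 2-fold and 98.2% at 4-fold, none with the wrong sign. The simulated rises and falls were nearly balanced, and no shift of all genes between the groups was simulated. False calls and wrong signs that come from such a shift were therefore not tested. The simulated changed list, drawn from raised genes only, was called, and 0 of 20 random lists of unchanged genes. Genes were simulated independently of one another, so this does not test camera's preset correlation.

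Alternatives fixed before the data were examined were a pseudocount of 0.1, every gene above 0 in any sample, an adjusted p under 0.01, no robust step, the replicate number as a block, leaving out each sample, an estimated correlation, and fry. Those added after seeing the data were median-of-ratios, upper-quartile and equal-sum scaling of TPM, a filter of 5 TPM, limma on the deposited log2 values, voom on recovered reads, and limma's treat against 2-fold. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9) was used for reading tables and drawing.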

Results

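Poly(A) RNA was sequenced from RAW264.7 cells, a mouse macrophage line, in 2 states. The cells carried a Cas9 plasmid without a guide RNA, which makes them the control line for a knockout of E4BP4, the transcription factor encoded by Nfil3. M1 cells had received lipopolysaccharide (LPS, a bacterial cell wall component that activates Toll-like receptor 4) at 100 ng/ml together with interferon-γ at 50 ng/ml. M0 cells had received neither. Each group held 3 samples, and the medium contained 25 mM glucose. Between 15615639 and 20283180 reads per library were assigned to genes, which is 83.5% to 86.7% of the library totals in the headers of the authors' deposited table. For a transcript of 2000 bases, 1 TPM (a read count scaled by transcript length and by the library) stood for at least 26.5 reads in the shallowest library. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The first principal component of the 11297 tested genes separated M1 from M0 and carried 95.3% of the variance. Across genes, the lowest Pearson correlation was 0.995 within either group, and the highest between groups was 0.874.

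The comparison of M1 with M0 asks how gene expression in this line differs after LPS and interferon-γ. Among the 10 genes with the largest increases, with small RNAs, predicted genes and genes below 10 TPM in the higher group passed over, was Gbp2b (NM_010259, chromosome 3, 142594847 to 142619176, mm10), a guanylate-binding protein, which went from 2.07 ± 0.166 to 3099 ± 48.8 TPM (mean ± SD, n = 3 in this and all following values). Cxcl10 (NM_021274, chromosome 5, 92346639 to 92348889), a chemokine that attracts T cells, went from 2.86 ± 0.351 to 3113 ± 12.9 TPM. Acod1 (NM_008392, chromosome 14, 103047012 to 103056573), which makes itaconate, went from 1.04 ± 0.139 to 1199 ± 42.3 TPM. Nos2 (NM_001313922, chromosome 11, 78925291 to 78960226), the inducible nitric oxide synthase, went from 0.161 ± 0.0417 to 563 ± 51.7 TPM. The other 6 of the 10 largest increases were those of Serpina3g, Gbp5, Iigp1, Cxcl9, Cxcl11 and Saa3, each below 0.2 TPM on average in M0 and between 437 and 891 TPM in M1. Their M0 level rested on 3 to 9 reads over the 3 libraries. The 10 fitted log2 fold changes lay between 8.56 and 9.98 on the log2(TPM + 1) scale, which understates the change of genes near 0 in M0, and the largest of the 10 adjusted p-values was 2.1e-11 (limma-trend). Reads of the guanylate-binding proteins, and of Serpina3g and its neighbours, can be shared between similar copies, so the split among family members is uncertain.

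The 10 largest decreases under the same rule were smaller. Ankrd37 (NM_001039562, chromosome 8, 45996908 to 45999850), an ankyrin repeat gene known to respond to hypoxia, fell from 45.3 ± 2.53 to 1.29 ± 0.434 TPM, a log2 change of -4.35 (SE 0.13, limma adjusted p = 2.0e-09). Cd300lb, an activating receptor of myeloid cells, fell from 54.5 ± 3.48 to 3.17 ± 0.0617 TPM. The circadian repressor Bhlhe41 fell from 31.9 ± 2.81 to 1.71 ± 0.29 TPM. The chemokine receptors Cxcr4 and Cx3cr1 fell from 18.1 ± 1.04 to 0.61 ± 0.149 TPM and from 14.3 ± 0.713 to 0.496 ± 0.109 TPM. Kif21b, a kinesin, Vsir, an inhibitory immune receptor, Lbh, Cd28 and Rasgrp3 made up the rest of the 10, with log2 changes between -3.60 and -3.14.

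**Figure D1:**
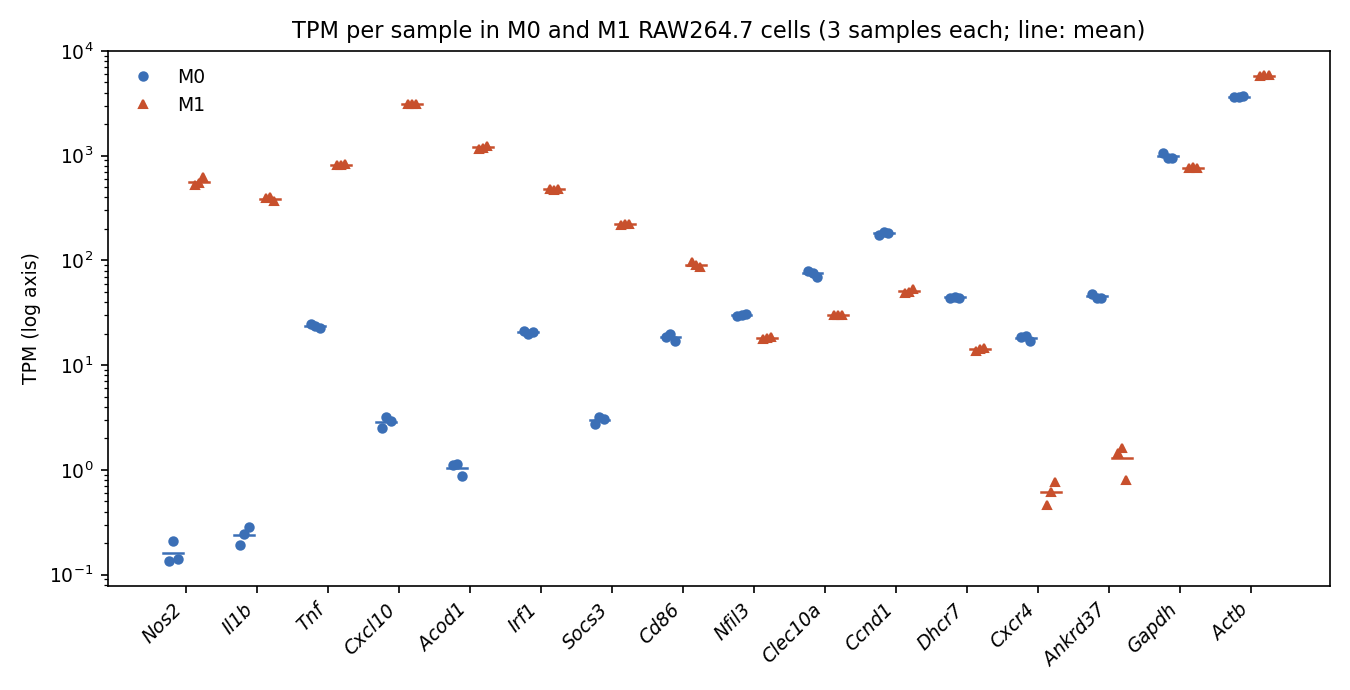
TPM of 16 genes in each of the 3 M0 samples (blue circles) and 3 M1 samples (orange triangles), on a log axis, with a line at each group's mean. Nos2 lies between 0.134 and 0.209 TPM in M0 and between 522 and 621 TPM in M1, whereas Gapdh differs little, with means of 989.7 and 764 TPM.

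In all, 2111 of the 11297 tested genes were higher in M1 and 6944 were lower (limma-trend on log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05), and 732 and 1281 of them differed by at least 2-fold. The median log2 fold change of all tested genes was -0.31, so the TPM scale placed most genes lower in M1. After TPM had been divided by median-of-ratios factors, which bring that median to 0.02, 4305 genes were higher and 4002 were lower, and 1009 and 652 differed by at least 2-fold. The share of calls that were higher was 23.3% on the TPM scale and 51.8% after rescaling. Of the genes lower on the TPM scale, 510 were higher after rescaling, while no gene went the other way. "Rose" and "fell" refer to the TPM scale in what follows, and list counts after rescaling stand beside those that differ. With an estimated correlation, no list was called after rescaling, where the lowest adjusted p was 0.065 (camera).

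**Figure D2:**
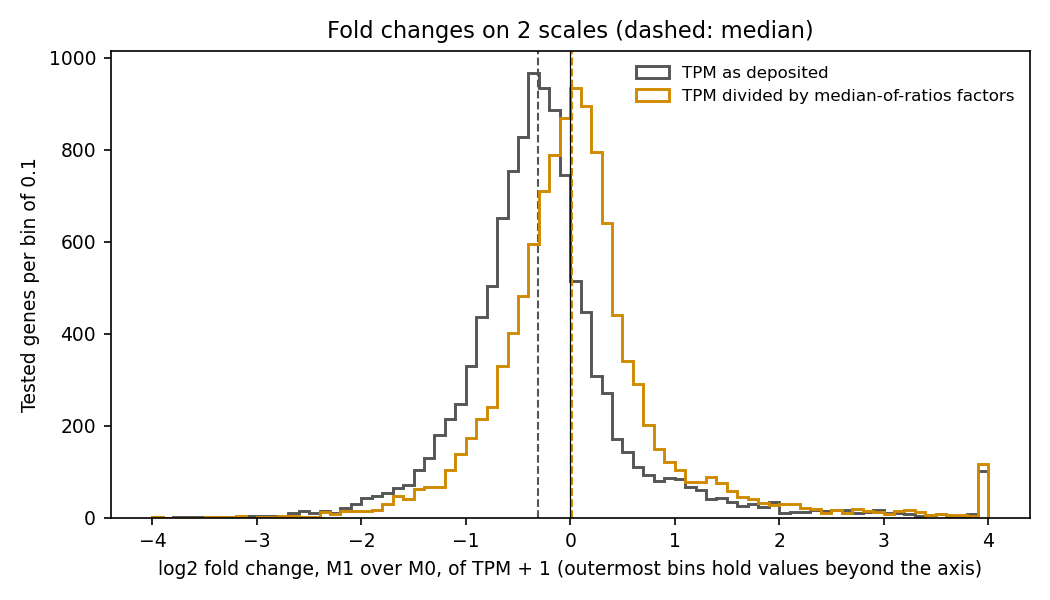
Number of tested genes per bin of 0.1 against the log2 fold change of M1 over M0, on TPM as deposited (grey) and after division by median-of-ratios factors (orange), with dashed lines at the medians of -0.31 and 0.02. The whole distribution is displaced, and the outermost bins also hold the values beyond the axis.

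Cytokine and chemokine genes rose. Of 16 tested inflammatory cytokines, 15 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.2e-14, and adjusted p = 0.027 with an estimated correlation). Il1b went from 0.239 ± 0.0464 to 387 ± 20.1 TPM. Tnf rose 34.7-fold, from 23.7 ± 1.00 to 821 ± 5.95 TPM. Il6, listed at 0 in 1 M0 library, reached 37.0 ± 1.69 TPM in M1. Il12b stayed below the filter for testing, at 0.0613 ± 0.0855 TPM in M0 and 0.824 ± 0.0737 TPM in M1. These levels rested on 7 and 101 reads over each group's 3 libraries. For Il12b the authors' deposited table gave a log2 fold change of 4.07. The member that fell was Tnfsf9, from 41.4 ± 1.96 to 19.3 ± 0.472 TPM. Il10, an anti-inflammatory cytokine, fell from 2.13 ± 0.68 to 0.268 ± 0.0725 TPM (limma adjusted p = 5.4e-06). Of 17 chemokines, 14 rose and 3 fell, also over the list alone (camera adjusted p = 1.7e-12). The chemokine call was lost with an estimated correlation (adjusted p = 0.11). Cxcl14 and Ccl24 were among the 3 that fell, from 2.28 ± 0.179 to 0.64 ± 0.15 TPM and from 1.69 ± 0.0608 to 0.796 ± 0.125 TPM. Ccl24 rested on 96 reads in M0 and 51 in M1. The authors' deposited table gave it a log2 fold change of -0.68 without a call.

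Interferon-responsive genes rose together. All 45 tested interferon-stimulated antiviral genes rose (camera adjusted p = 6.0e-41, and adjusted p = 0.038 with an estimated correlation), as did all 19 tested guanylate-binding proteins and immunity-related GTPases (camera adjusted p = 8.6e-25, and adjusted p = 0.038 with an estimated correlation). The counts were the same adjusted over the list alone and after rescaling. Ifit1, an RNA-binding antiviral protein, went from 1.90 ± 0.0333 to 625 ± 21.9 TPM, and Ifit2 from 7.11 ± 0.47 to 639 ± 25.5 TPM. Of 23 genes of MHC class I presentation, 21 rose and 2 fell, also over the list alone (camera adjusted p = 5.8e-17, and adjusted p = 0.027 with an estimated correlation). Tap1, a subunit of the peptide transporter, rose 18.5-fold to 306 ± 8.37 TPM, and Nlrc5, the class I transactivator, rose 21.2-fold to 53.4 ± 1.35 TPM. The 2 that fell were the chaperones Pdia3 and Calr, whose log2 changes of -0.34 and -0.37 became 0.03 and -0.01 after rescaling and were no longer called.

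Of 11 MHC class II genes, 3 were expressed highly enough to be tested, too few for a list test, and the others reached at most 0.728 TPM in any library. H2-DMa fell from 4.03 ± 0.52 to 1.90 ± 0.24 TPM, and the only falling count adjusted over the list alone was also 1. Cd74, the invariant chain, had 368 ± 22.7 TPM in M0 and 394 ± 4.13 TPM in M1 and was not called (limma adjusted p = 0.092), although it was higher after rescaling (log2 change 0.46, adjusted p = 4.5e-05). Ciita, the class II transactivator, had 0.0137 ± 0.0131 and 0.203 ± 0.0419 TPM. H2-Aa was listed at 0 in the 3 M0 libraries and at 0.058 to 0.363 TPM in the M1 libraries.

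Markers of the M1 state rose and those of the M2 state were mixed. All 14 tested M1 markers rose, also over the list alone (camera adjusted p = 9.4e-17, and adjusted p = 0.038 with an estimated correlation). The costimulatory gene Cd86 rose 4.93-fold to 90.9 ± 5.13 TPM, whereas Cd80 rose from 1.45 ± 0.087 to 2.20 ± 0.446 TPM. Ptgs2, the inducible cyclooxygenase, rose 45.5-fold to 508 ± 22 TPM. Of 9 tested M2 markers, 2 rose and 7 fell, on both scales and over the list alone, and the list was not called (camera adjusted p = 0.52). The lectins Clec10a and Mgl2, which are close copies, fell from 75.1 ± 5.08 to 30 ± 0.252 TPM and from 44.4 ± 4.14 to 17.9 ± 0.313 TPM. Ccl22 reached 4.55 ± 0.46 TPM and Klf4 rose 1.76-fold to 8.72 ± 0.946 TPM. Arg1 and Mrc1, commonly used M2 markers, were too low to be tested, with Arg1 at 0.174 ± 0.0719 and 0.124 ± 0.0372 TPM and Mrc1 at 0.321 ± 0.0139 and 0.29 ± 0.053 TPM in M0 and M1.

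Among 30 tested NF-κB targets and feedback regulators, 29 rose and 1 was not called (camera adjusted p = 2.7e-26), with the same counts over the list alone. The call was lost with an estimated correlation (adjusted p = 0.051). Icam1, an adhesion molecule, rose 18.4-fold to 518 ± 11.3 TPM and Traf1 rose 28.5-fold to 103 ± 2.46 TPM. Tnip3 had 151 ± 8.87 TPM in M0 and 147 ± 3.0 TPM in M1, and after rescaling its sign turned and it was higher in M1 (log2 change 0.33). Of 20 regulators of cytokine signalling, 10 rose and 8 fell, against 14 and 4 after rescaling (camera adjusted p = 0.00046, and adjusted p = 0.43 with an estimated correlation). The cytokine signalling inhibitors Socs3 and Socs1 rose 73.4-fold and 182-fold, to 222 ± 4.10 and 198 ± 5.77 TPM. Dusp6, an ERK phosphatase, fell from 49.4 ± 1.73 to 11.7 ± 0.272 TPM and Ptpn6 from 263 ± 11.7 to 187 ± 6.71 TPM. Dusp1 had 21.3 ± 0.717 and 22.2 ± 1.18 TPM and was called higher only after rescaling.

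Of 29 IRF, STAT and AP-1 transcription factors, 18 rose and 10 fell, against 19 and 7 after rescaling (camera adjusted p = 3.7e-07, and adjusted p = 0.19 with an estimated correlation). Irf1 rose 23.3-fold to 478 ± 4.76 TPM and Irf7 rose 21.1-fold to 275 ± 4.99 TPM. Cebpa and the hypoxia-inducible factor Epas1 fell 4.12-fold and 3.99-fold, to 3.41 ± 0.0508 and 5.58 ± 0.485 TPM. Ets2 had 85.4 ± 3.36 and 85.3 ± 6.06 TPM and was higher after rescaling (log2 change 0.36).

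Nfil3 (NM_017373, chromosome 13, 52967209 to 52981039), which encodes E4BP4, fell from 30.1 ± 0.803 to 18.2 ± 0.425 TPM in M1, a log2 change of -0.70 (SE 0.05, limma adjusted p = 1.9e-07) with every M1 sample below every M0 sample. After rescaling the log2 change was -0.35 (adjusted p = 5.1e-05), and the authors' deposited table gave -0.37. Of 14 circadian and PAR bZIP factors, none rose and 12 fell, also over the list alone, against 3 and 8 after rescaling (camera adjusted p = 0.039). The call was lost with an estimated correlation (adjusted p = 0.51). Bhlhe40 fell 5.22-fold to 2.79 ± 0.339 TPM. Cry1 had 6.70 ± 0.352 and 5.85 ± 0.655 TPM, was not called, and had the opposite sign after rescaling, again without a call.

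Cell death and nitric oxide genes changed in both directions. Of 21 inflammasome and cell death genes, 14 rose and 6 fell, against 15 and 5 after rescaling (camera adjusted p = 8.5e-06, and adjusted p = 0.10 with an estimated correlation). The death receptor Fas rose 35.1-fold to 154 ± 6.57 TPM and Casp4, a sensor of intracellular LPS, rose 15.6-fold to 300 ± 13.4 TPM. Gsdme fell 5.72-fold to 1.52 ± 0.273 TPM. Aim2 had 53 ± 2.16 and 55.8 ± 2.47 TPM and was called higher only after rescaling. Of 17 genes of nitric oxide, arginine and the NADPH oxidase, 10 rose and 4 fell, against 13 and 3 after rescaling (camera adjusted p = 6.2e-05, and adjusted p = 0.16 with an estimated correlation). The arginine transporter Slc7a2 rose 22.2-fold to 111 ± 4.03 TPM. Spr fell from 98.1 ± 6.42 to 62.0 ± 0.931 TPM. Cyba had 505 ± 17.8 and 527 ± 29.4 TPM and was called higher only after rescaling.

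Cell cycle genes fell. Of 31 genes of G1/S and DNA replication, 29 fell and 1 rose, against 29 and 2 after rescaling, and 19 fell by at least 2-fold on the TPM scale, against 14 after rescaling (camera adjusted p = 1.7e-05, and adjusted p = 0.30 with an estimated correlation). Ccnd1, which encodes cyclin D1, fell 3.58-fold to 50.6 ± 2.75 TPM and Uhrf1 fell 3.32-fold to 32.4 ± 0.134 TPM. Rfc3 rose from 46.0 ± 0.42 to 54.3 ± 2.18 TPM. Mcm10 had 30.6 ± 1.53 and 33.2 ± 2.34 TPM and was called higher only after rescaling. All 35 tested genes of G2/M and mitosis fell on the TPM scale, whereas after rescaling 29 fell and 1 rose, and 8 fell by at least 2-fold on the TPM scale, against 2 after rescaling (camera adjusted p = 1.7e-05, and adjusted p = 0.31 with an estimated correlation). The median log2 change of the list was -0.78, and -0.44 after rescaling. The examples with the smallest p, Ccnf and Cdc25b, fell 3.01-fold and 2.98-fold, to 12.6 ± 0.317 and 13.1 ± 0.978 TPM.

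Sterol genes and glycolytic genes mostly fell. Of 23 genes of cholesterol synthesis and uptake, 21 fell and 1 rose, against 13 and 6 after rescaling (camera adjusted p = 0.012, and adjusted p = 0.54 with an estimated correlation). Dhcr7 fell 3.14-fold to 14.1 ± 0.378 TPM and Acat2 fell 2.49-fold to 22.9 ± 0.603 TPM. Idi1 had 16.7 ± 0.989 and 15.1 ± 1.01 TPM and was called higher after rescaling, with its sign turned. Of 25 glycolysis genes, 21 fell and 4 rose, against 17 and 4 after rescaling. This list was not called on the TPM scale (camera adjusted p = 0.099) and was called lower after rescaling (adjusted p = 0.023, and adjusted p = 0.21 with an estimated correlation). Pdk1 fell 4.55-fold to 7.58 ± 0.475 TPM and Eno2 fell 2.16-fold to 22.5 ± 0.916 TPM. Slc2a6, a lysosomal hexose transporter, rose 4.97-fold to 402 ± 6.83 TPM, and Hk3 rose 1.75-fold to 151 ± 0.97 TPM.

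More ribosomal genes were called higher after rescaling, which moved all genes by the same factors. Of 28 ribosome biogenesis genes, 8 rose and 8 fell, with 7 and 8 over the list alone, against 22 and 0 after rescaling. The list was called higher on both scales (camera adjusted p = 0.039 on TPM, and adjusted p = 0.22 with an estimated correlation; adjusted p = 0.00048 after rescaling, and adjusted p = 0.086 with an estimated correlation). Nop58 and Rrp12 rose from 167 ± 4.03 to 224 ± 4.92 TPM and from 11.8 ± 0.747 to 22 ± 3.42 TPM. Nop10 fell from 117 ± 11.2 to 84.8 ± 5.24 TPM and Wdr12 from 34.9 ± 0.589 to 27.8 ± 0.944 TPM, and neither was called after rescaling, where the sign of Wdr12 turned. Npm1 had 778 ± 12.1 and 827 ± 16.2 TPM and was called higher only after rescaling. Of 48 cytosolic ribosomal protein genes, 1 rose and 9 fell (camera adjusted p = 0.17), with 1 and 4 over the list alone, whereas 46 were higher and none lower after rescaling (adjusted p = 1.9e-05, and adjusted p = 0.61 with an estimated correlation). Of 15 reference genes, 3 rose and 7 fell, against 9 and 3 after rescaling (camera adjusted p = 0.52). Actb rose from 3639 ± 42.2 to 5829 ± 72.0 TPM and was called higher on both scales, with log2 changes of 0.68 on TPM and 1.04 after rescaling. Gapdh fell from 989.7 ± 68.2 to 764 ± 11.6 TPM, and after rescaling its log2 change of -0.01 was not called.

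**Figure D3:**
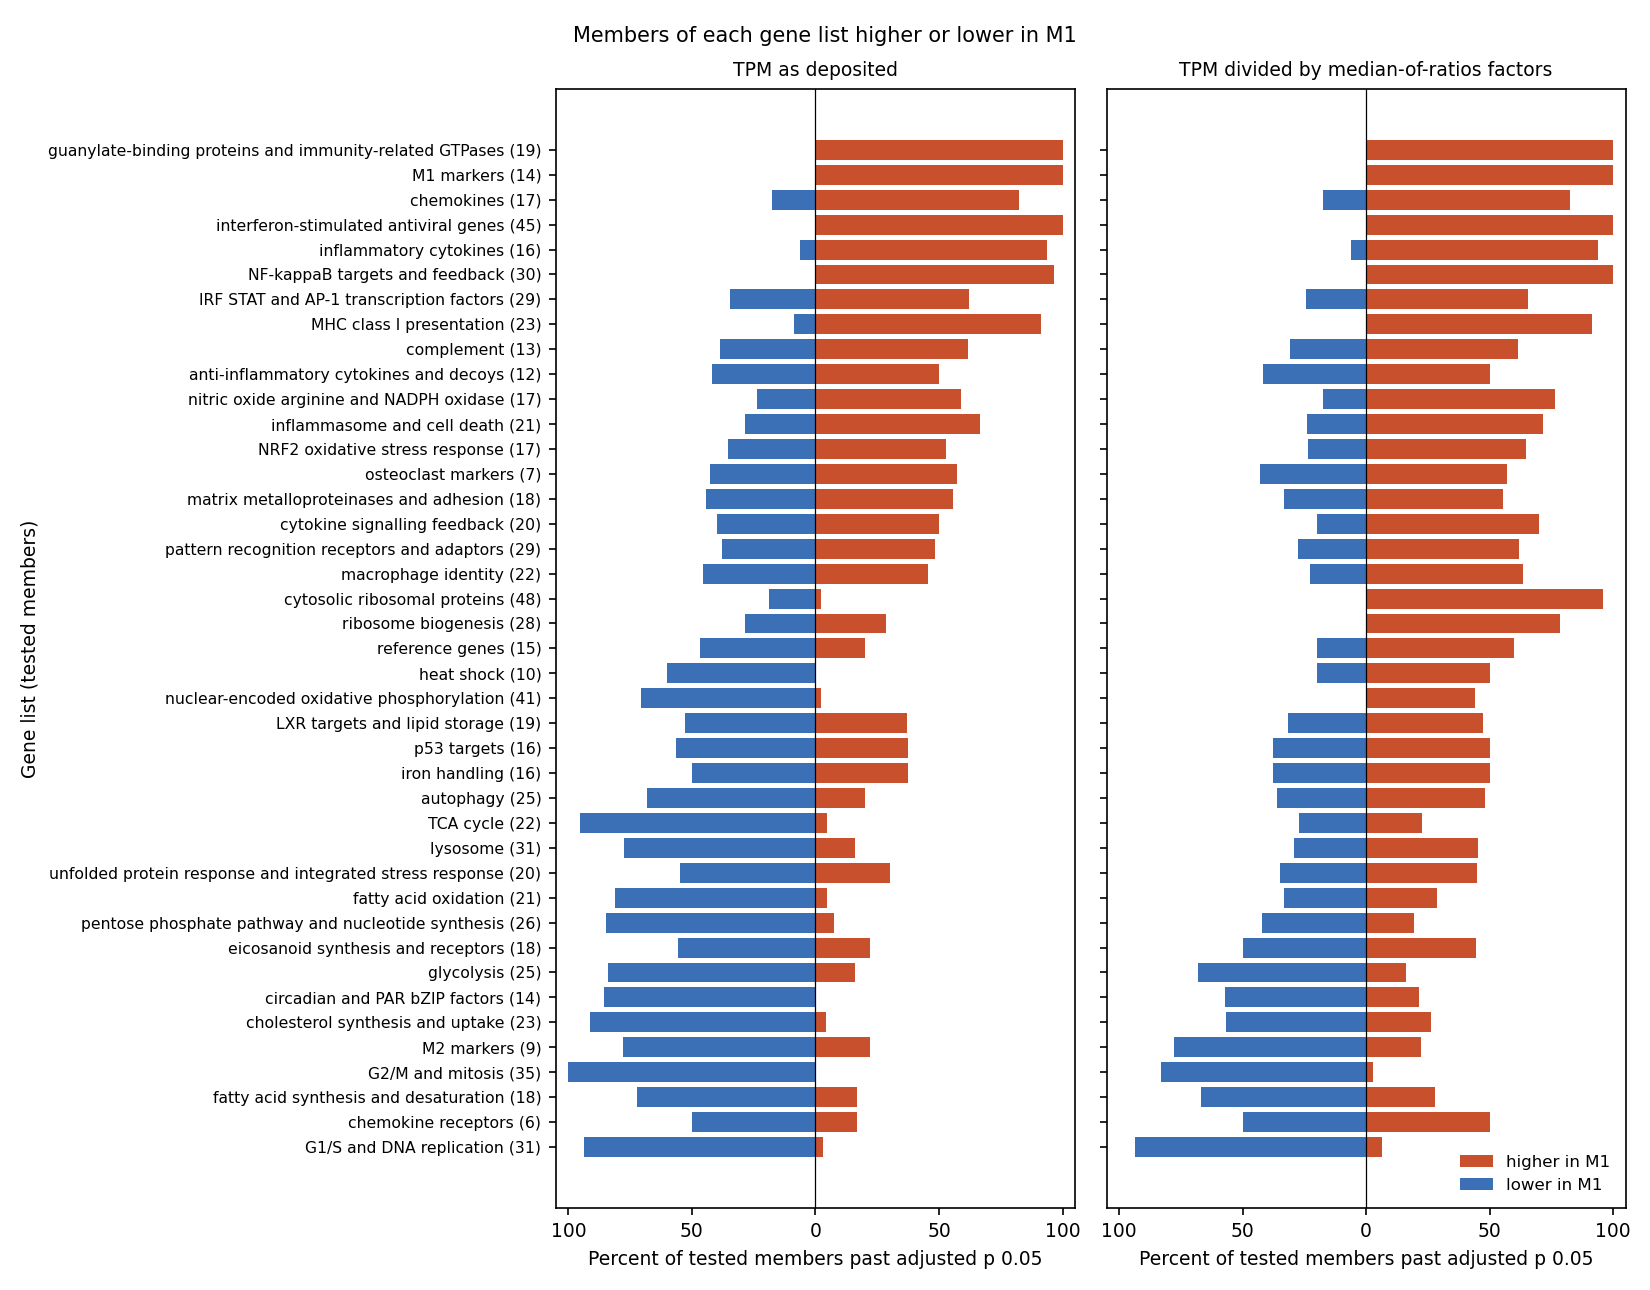
Percent of the tested members of each of 41 gene lists that were higher (orange, to the right) or lower (blue, to the left) in M1 at an adjusted p under 0.05, on TPM as deposited (left) and after division by median-of-ratios factors (right). All 45 interferon-stimulated antiviral genes are higher on both scales, whereas ribosomal protein genes are called higher in 1 of 48 cases on the left and in 46 of 48 on the right.

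For the other lists, the number higher is given before the number lower and the adjusted p of limma's camera after them. On the TPM scale these were anti-inflammatory cytokines and decoys (6 and 5 of 12, adjusted p = 0.019), pattern recognition receptors and adaptors (14 and 11 of 29, 18 and 8 after rescaling, adjusted p = 0.0032), the NRF2 oxidative stress response (9 and 6 of 17, 11 and 4 after rescaling, adjusted p = 0.024), macrophage identity (10 and 10 of 22, 14 and 5 after rescaling, adjusted p = 0.039), and matrix metalloproteinases and adhesion (10 and 8 of 18, 10 and 6 after rescaling, adjusted p = 0.019). These 5 calls toward M1 were lost with an estimated correlation, at adjusted p = 0.25, 0.40, 0.24, 0.22 and 0.31, and after rescaling, at adjusted p = 0.23, 0.059, 0.10, 0.060 and 0.23. The TCA cycle list (1 and 21 of 22) was called lower at adjusted p = 0.039, and neither an estimated correlation (adjusted p = 0.31) nor rescaling (5 and 6, adjusted p = 0.94) kept that call. Lists without a camera call on either scale were pentose phosphate pathway and nucleotide synthesis (2 and 22 of 26, 5 and 11 after rescaling), nuclear-encoded oxidative phosphorylation (1 and 29 of 41, but 18 and 0 after rescaling, camera adjusted p = 0.0502), fatty acid oxidation (1 and 17 of 21, 6 and 7), LXR targets and lipid storage (7 and 10 of 19, 9 and 6), lysosome (5 and 24 of 31, 14 and 9), autophagy (5 and 17 of 25, 12 and 9), the unfolded protein and integrated stress responses (6 and 11 of 20, 9 and 7), heat shock (0 and 6 of 10, 5 and 2), p53 targets (6 and 9 of 16, 8 and 6), osteoclast markers (4 and 3 of 7 on both scales) and chemokine receptors (1 and 3 of 6, 3 and 3). The median and the camera direction had opposite signs for LXR targets, the stress responses, p53 targets, chemokine receptors, both ribosomal lists and reference genes, with the median below 0 on the TPM scale.

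No fibroblast, epithelial, B cell or endothelial marker reached the filter for testing, and their highest values in any library were 1.06, 0.097, 0.303 and 0.752 TPM. Of the T cell markers Lck alone was tested and rose from 2.54 to 12.1 TPM, while no other marker on that list exceeded 0.115 TPM. For neutrophil and dendritic cell markers, 2 genes each were tested, of which 1 rose and 1 fell in both cases, although after rescaling no neutrophil marker was lower. The dendritic cell marker that rose was Batf3, from 17.2 to 42.1 TPM, which is also on the list of IRF, STAT and AP-1 factors.

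The authors' deposited table lists 4290 genes higher and 3881 lower in M1 at an adjusted p under 0.05. Among 10769 genes with a test in both, 2005 of the 2020 genes that rose on the TPM scale and 3464 of the 6618 that fell had the same call in the authors' deposited table, and 386 of those that fell were called higher there. After rescaling, 3797 of 4122 higher genes and 3437 of 3819 lower genes had the same call and none the opposite one. The rescaled TPM and the authors' deposited table come from the same libraries, and the rescaling was chosen after seeing the data. Their overlap is therefore not independent support. The log2 ratio of mean TPM differed from the fold change in the authors' deposited table by a median of -0.36, and 98.0% of 10751 genes lay within 0.1 of that median.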

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

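The scalings, the 5 TPM filter, the deposited log2 values, voom, treat and the test of other splits were chosen after seeing the data. Against 2111 genes higher and 6944 lower, median-of-ratios scaling gave 4305 and 4002, upper-quartile scaling 3439 higher, the deposited log2 values 4152 and 3865, and voom on recovered reads 4242 and 4152. Against 732 genes higher and 1281 lower by at least 2-fold, median-of-ratios scaling gave 652 lower, upper-quartile scaling 796 lower and the deposited log2 values 733 lower. Voom gave 1121 higher and 1064 lower at 2-fold, and treat 759 lower. The 2 scalings shift every gene by construction and treat asks for a larger change. Voom used median-of-ratios factors too. The deposited tables differ by a median of -0.36, with 98.0% of genes within 0.1 of it. Lists called lower numbered 5, but 10 with every gene above 0, 2 at an adjusted p under 0.01, 3 with the 5 TPM filter, 0 with an estimated correlation and 20 with fry, which does not compare a list with other genes. Lists called higher numbered 18, but 5 with an estimated correlation. The other settings kept these counts within 1.5 times.

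Leaving out 1 sample gave 1990 to 2076 genes higher and 6606 to 6997 lower, 719 to 752 and 1264 to 1346 at 2-fold, and 17 to 19 lists higher and 4 to 6 lower. With the replicate number as a block, 2143 genes were higher and 7016 lower, 734 and 1273 at 2-fold, with 18 and 5 lists. No pairing by number was visible: the residuals of same-numbered samples correlated at 0.07, -0.08 and 0.04. M0 replicates 1 and 2 correlated best with another number, and M0 replicate 3 with its own. With 3 samples per group this cannot tell whether same-numbered samples were handled together.

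Of 107 tested genes followed, 89 kept direction and call under each setting that gave them a value. A few had no value among the deposited log2 values or under the 5 TPM filter. These turned sign, in the order median-of-ratios, upper-quartile, deposited log2 values, voom: Tnip3 (0.33, 0.22, 0.32, 0.31), Ets2 (0.36, 0.25, 0.35, 0.34), Cry1 (0.14, 0.049, 0.14, 0.15), Slc11a1 (0.30, 0.19, 0.30, 0.28), Idi1 (0.21, 0.10, 0.21, 0.20) and Mcat (0.28, 0.18, 0.28, 0.28). None of these 6 was called on the TPM scale. Pdia3 (0.026, 0.025, 0.0090) and Wdr12 (0.036, 0.027, 0.021), called lower on TPM, turned under all but upper-quartile scaling. Ets2, near 0 on TPM, lay between -0.060 and 0.032 when single samples were left out, without a call and with its sign turned in 4 of the 6 cases. Cd74 and Idi1 without M0 replicate 1, and Cry1, Cyba and Npm1 without M1 replicate 3, gained a call (log2 changes 0.15, -0.18, -0.25, 0.11 and 0.10), as did Cry1 with the block (-0.17), the only call among these genes that the block changed, and Cry1 and Idi1 with equal column sums (-0.22 and -0.18).

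With 10 splits of the 6 samples into 3 and 3, no share under 0.05 can be reached. The real split called 9055 genes and the highest other 0, with 1 of the 10 splits as large; at 2-fold it called 2013 and the highest other 0, again 1 of 10. For gene lists the real split called 23 and the highest other also 23, so 2 of 10 were as large. Every other split here leaves 2 samples of one group against 1 on each side and so keeps part of the group difference. Much of that difference enters the spread within each side, so a count of 0 genes was nearly fixed in advance. Camera with the preset correlation calls lists in these splits although no single gene is called.

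Alternatives written for deposited raw counts were not run, and the reads recovered from TPM were used with voom only. Left out were other size factors, count filters, a non-robust fit and treat within a count model, a second count test, and CPM for levels. Depth limits low genes, since 3 reads of a 2000-base transcript stood for 0.0872 to 0.113 TPM, depending on the library. At the same TPM a shorter transcript rests on fewer reads, so the 1 TPM filter asks for fewer reads of microRNA rows.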

Other observations

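Among the tests in this part, those of the deposited tables against each other, of the interferon-γ response and of depth were chosen only after the results were seen. Genes of lipid mediators and of complement went both ways within each list. Of 18 tested eicosanoid genes, 4 rose and 10 fell, against 8 and 9 after rescaling, with the same counts adjusted over the list alone (camera adjusted p = 0.87, with a median below 0 and the test's direction above it). The inducible cyclooxygenase Ptgs2 rose as given above, and the prostaglandin E2 receptor Ptger4 rose 1.73-fold to 25.9 ± 1.95 TPM, while the constitutive cyclooxygenase Ptgs1 fell 3.20-fold to 34.0 ± 2.04 TPM and the leukotriene receptor Cysltr1 fell 4.47-fold to 3.77 ± 0.0993 TPM. Pla2g4a had 139 ± 3.32 and 145 ± 4.51 TPM and was called higher only after rescaling. Of 13 complement genes, 8 rose and 5 fell, also over the list alone, against 8 and 4 after rescaling (camera adjusted p = 0.0024, and adjusted p = 0.11 with an estimated correlation), and after rescaling the list was not called (adjusted p = 0.060). C3 rose 21.4-fold to 353 ± 25.6 TPM and Cfb went from 0.18 ± 0.0484 to 19.6 ± 0.265 TPM, whereas the C5a receptor gene C5ar1 fell 2.82-fold to 68.4 ± 3.71 TPM and Itgb2 fell from 166 ± 8.42 to 114 ± 3.52 TPM.

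Iron and fatty acid genes also went both ways. Of 16 iron handling genes, 6 rose and 8 fell, against 8 and 6 after rescaling (camera adjusted p = 0.22, with a median below 0 and the test's direction above it). Lcn2, which binds bacterial siderophores, was listed at 0 in 2 M0 libraries and reached 58.3 ± 4.33 TPM in M1, and the iron importer Slc11a2 rose 4.24-fold to 106 ± 4.16 TPM. The iron exporter Slc40a1 fell 3.58-fold to 4.88 ± 0.341 TPM and the haem oxygenase Hmox1 fell 3.10-fold to 37.1 ± 2.59 TPM. Slc11a1 had 185 ± 7.04 and 177 ± 7.36 TPM, with the opposite sign and a call after rescaling. Of 18 genes of fatty acid synthesis and desaturation, 3 rose and 13 fell, against 5 and 12 after rescaling. This list was not called on the TPM scale (camera adjusted p = 0.14) and was lower after rescaling (adjusted p = 0.040, and adjusted p = 0.53 with an estimated correlation). The desaturase Scd2 fell 6.46-fold, from 612 ± 22.7 to 94.7 ± 5.12 TPM, and Acsl3 fell 4.21-fold to 16.5 ± 0.963 TPM, while the acyl-CoA synthetases Acsl1 and Acsl5 rose 7.99-fold and 1.26-fold, to 236 ± 15.9 and 143 ± 4.77 TPM. Mcat had 27.0 ± 0.474 and 25.7 ± 1.03 TPM, with the opposite sign and a call after rescaling.

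More genes were lower than higher in M1 on the TPM scale. The 299 genes that rose at least 4-fold took 0.439% of the full TPM scale in M0 and 6.82% in M1, counting only the transcript listed for each gene. With them removed and TPM rescaled to what was left, the median log2 fold change of the other tested genes went from -0.33 to -0.24. That median lay between -0.25 and -0.23 on leaving out any 1 sample. With the remaining listed values set to equal sums instead, it was -0.22. Neither the removed genes nor unlisted transcripts enter those sums, so a share taken by either is argued against as the whole cause. Genes that rose by less than 4-fold stayed in the sums, among them Actb, at 3639 TPM in M0 and 5829 TPM in M1. A share taken by such abundant genes was therefore not tested and stays open. Length in the TPM denominator is argued against by recovered reads divided by all reads in genes, which use no length and had a median log2 ratio of -0.34. The tables differ by nearly one factor, with 98.0% of genes within 0.1 of the median difference, and whether total RNA per cell changed cannot be read from either without spike-ins.

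Some microRNA rows stood at high TPM although the libraries were poly(A)-selected. The tested rows were at most 138 bases long, so each read stood for more TPM than in a longer transcript. Rows near the 1 TPM filter therefore rest on few reads. They were still tested and could be called, such as Mir7219, at 1.29 ± 0.119 TPM in M0 and 0 in M1 (limma adjusted p = 8.4e-08). Such rows were also kept in the host comparison below. Mir6381 (chromosome 3, 142623860 to 142623946) went from 0.246 ± 0.427 to 1263 ± 35.3 TPM, and Mir5114 (chromosome 19, 44303171 to 44303231) fell from 1066 ± 67.8 to 159 ± 3.57 TPM. Of 209 tested microRNA rows, 136 (65.1%) overlapped an exon of another gene in GENCODE M21, Gbp2 for Mir6381, on the opposite strand, and Scd2 for Mir5114, on the same strand. Of 121 rows with a tested host, 106 (87.6%) had a log2 change of the host's sign, whether or not it was called, against 57.5% for randomly drawn hosts, so these rows may carry reads of the host transcript. The rows without such an exon, Mir6236 among them at 2557 ± 310.3 and 2358 ± 232.2 TPM, stay open.

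The class II chain genes H2-Aa, H2-Ab1 and H2-Eb1 and the transactivator Ciita stayed below 1 TPM in M1 although interferon-γ was given, unlike Cd74. Of the tested guanylate-binding proteins and immunity-related GTPases 100% rose, but LPS also induces such genes through interferon-β, so a missing response to interferon-γ stays open. Low depth is argued against by the 26.5 reads or more that stood behind 1 TPM of a 2000-base transcript. Ciita reached 52 reads over the 3 M1 libraries, against 3 in M0. Whether class II would appear at another time, or is limited in this line by Ciita, was not tested, since the series holds 1 line and the labels give no duration.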
